A study of Arabidopsis thaliana with 4 samples.

How the data were processed

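Roots of Arabidopsis thaliana nai1-1 plants, a mutant deficient in ER bodies, were compared with roots of wild-type Col-0 plants on 4 two-colour Agilent oligonucleotide arrays. ER bodies are spindle-shaped compartments of the endoplasmic reticulum found in Brassicaceae. Per the labels' protocols, plants were 20 days old and had grown at 22 °C in continuous light on MS medium with 1% sucrose and 0.5% gellan gum. Mutant and control plants shared a plate, and RNA of 3 plants was pooled for each genotype. From 5 µg of total RNA, labelled targets were made by linear amplification. Both genotypes were on each array. The labels put nai1-1 in Cy3 on arrays 1 and 4 and in Cy5 on arrays 2 and 3, so each dye orientation was used on 2 arrays. The labels number the arrays as replicates 1 to 4 of 1 comparison but do not say whether the arrays came from separate pools of plants. The p-values therefore measure the spread between these 4 arrays, which may be technical.

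The deposited values are 1 log10 ratio per probe and array, made with Agilent Feature Extraction 7.1 per the submitters' processing notes. The software's background and dye correction settings are not given in the sources used here. That software writes its log ratio as Cy5 over Cy3. This orientation was taken from the software's convention and is not stated by the submitters. Across probes with 1 named gene, deposited values of arrays with opposite dye orientation correlated negatively (Pearson r from -0.33 to -0.75) and those of arrays with the same orientation positively (0.50 and 0.51). Single arrays had therefore not been turned relative to the others before deposition. Across all probes r was between -0.144 and 0.132 for opposite orientations, and 0.444 and 0.662 for the same orientation. The deposited log10 ratios were divided by 0.301 to give log2 ratios, and arrays 1 and 4 were turned so that every value is nai1-1 over Col-0. No other normalization was applied. Array medians were 0, 0, -0.00 and 0 on the log2 scale. The median absolute deviations were 0.39, 0.33, 0.22 and 0.19 on arrays 1 to 4. The 22575 probes had no missing values, but 1016 probes held a log ratio of exactly 0 on at least 1 array and 143 on all 4 arrays. Intensities, detection flags and control flags were not analysed here, so dim spots, saturated spots and control spots were not removed. The number of arrays limits the precision of each ratio.

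Probes were named through the platform annotation with symbols updated by Entrez identifier through a RefSeq gene table for assembly TAIR10.1. Of the probes, 9335 had 1 gene, 40 had several and 13200 were not listed. The probes with 1 gene covered 9253 genes. The identifiers of 9317 of these probes matched the RefSeq table, and 18 probes kept the annotation's own symbol. Probes with several genes were not named, and a probe that is not listed is unnamed here, not without a gene. Among the genes chosen in advance, MEB1, MEB2, PBP1, TSA1 and BGLU18 had no named probe and were not analysed here.

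The comparison of nai1-1 with Col-0 was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 22575 probes, with a genotype term and a dye term, a two-sided moderated test and Benjamini-Hochberg adjustment at 0.05. All adjusted p-values of single genes come from this fit unless another is named. The dye term of the same fit was tested at the same threshold. A set of 20 gene lists (373 loci) was written from textbook knowledge, and those with at least 3 measured genes were tested with limma camera at its preset correlation of 0.01, with 1 mean value per gene over 9253 genes. Camera with an estimated correlation and limma fry were run beside it. The former tests on the residual degrees of freedom of the arrays, which were few, so a missing call carries little weight. Correlations between arrays are given across probes, which are not independent replicates, so they carry no p-value. Arrays were compared before averaging, and no pair held identical values.

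Named genes followed a rule. NAI1 came first, then PYK10, BGLU21, BGLU22 and NAI2 whatever their values and other ER body genes past the threshold. The 10 largest changes in each direction among probes past the threshold with the same sign on 4 arrays followed, then up to 4 members of each other list by smallest p, and up to 3 genes with the largest dye effect. Design, lists, naming rule and most alternatives were fixed before the data were examined. A list of rapid touch and wound response genes and the alternatives marked as such in the closing section were added later.

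On simulated data with the real probes and spreads, the fit on 22575 probes recovered 55% of probes changed by 1 log2 unit and 97% of those changed by 2, with 0 unchanged probes called. On the 21559 probes without an exact 0 it recovered 97% and 100%, with 17 unchanged probes called. The simulated arrays varied independently, so these shares and counts do not apply if the real arrays share RNA. Camera recovered a simulated shift of -0.5 in 20 of 20 runs for each of the 8 tested lists, among 9253 genes. Genes varied independently in these runs, while in the real data the estimated correlation within lists ranged from -0.332 to 0.951. The runs therefore do not show how camera performs where list members co-vary. In these runs camera also called unshifted lists: 4 times with the other jacalin-related lectins shifted, 2 times each with ER body and heat shock genes shifted, 1 time each with aliphatic glucosinolate and ER chaperone genes shifted, and 0 times with the remaining 3 lists.

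Alternatives were a fit without the dye term, median centring, scaling to 1 median absolute deviation, quantile normalization, array weights, robust eBayes, a minimum change of 2-fold, a threshold of 0.01, gene-level values, probes without an exact 0, named probes alone, values left unturned, and leaving out each array in turn. Added after the data had been seen were fits in which arrays 1 and 2 and arrays 3 and 4 were averaged as 2 replicates, the other pairing of opposite dyes, and fits that combined these choices with leaving out exact 0 values.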

Results

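Relative transcript abundance was measured in roots of nai1-1, an ER body-deficient mutant, against roots of Col-0 on 4 two-colour arrays that each carried both genotypes. Arrays 1 and 4 had nai1-1 in Cy3 and arrays 2 and 3 had it in Cy5. Each array gave a ratio for 22575 probes, of which 9335 could be assigned to 1 gene. All values below are log2 ratios of nai1-1 over Col-0, means of 4 arrays (n = 4) with the standard error (SE) of the limma fit, and negative values mean a lower transcript level in the mutant. This direction rests on the Cy5 over Cy3 convention of the extraction software together with the dyes in the labels, and under the opposite convention every fall below would be a rise and every rise a fall.

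The first question was whether the mutated gene and the genes tied to ER bodies differed between the genotypes. NAI1 (AT2G22770), a basic helix-loop-helix transcription factor needed for ER body formation, had a log2 ratio of -0.70 ± 0.19 (SE, n = 4) and was below Col-0 on 4 of 4 arrays, at -0.77, -1.21, -0.21 and -0.60. It did not pass the threshold (adjusted p = 0.259). The labels do not say whether the nai1-1 lesion lowers the transcript or where the probe lies relative to it, so this value does not check the labels.

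The list named ER body genes here holds genes tied to ER bodies. Some were found by others in nai1 roots, so membership does not place a gene's product in ER bodies. Of its 18 genes, 11 were measured: 8 fell in nai1-1, 0 rose and 3 did not pass. Of the 8, 5 encode jacalin-related lectins, a family of carbohydrate-binding proteins: JAL22 (AT2G39310) fell by 4.99 ± 0.20 on the log2 scale, which is 31.8-fold, JAL33 (AT3G16450) fell by 4.53 ± 0.20, JAL31 (AT3G16430) fell by 3.67 ± 0.17, and JAL23 (AT2G39330) fell by 2.92 ± 0.12. JAL34 (AT3G16460) fell by 1.52 ± 0.13 on 1 probe (adjusted p = 0.0464), while its second probe, at -1.64 ± 0.17, did not pass (adjusted p = 0.0646). NAI2 (AT3G15950), an ER body component required for the formation of these bodies, fell by 2.81 ± 0.11 (adjusted p = 0.0181). PYK10 (AT3G09260), the beta-glucosidase that is the main protein of root ER bodies, fell by 2.01 ± 0.11 (adjusted p = 0.032), with values between -2.32 and -1.68 on the 4 arrays. AT1G54010, a GDSL-like lipase also called GLL23, fell by 1.62 ± 0.11 (adjusted p = 0.0346).

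The 3 ER body genes that did not pass were 2 beta-glucosidases and AT1G54020. BGLU22 (AT1G66280) was at -0.69 ± 0.16 (adjusted p = 0.21) and BGLU21 (AT1G66270) at -0.37 ± 0.24 (adjusted p = 0.59). BGLU21 was above Col-0 on array 1, at 0.56, and between -0.76 and -0.64 on the other 3 arrays. AT1G54020, a locus next to AT1G54010 in the gene table, was at 0.06 ± 0.11 (adjusted p = 0.869). Probe sequences were not analysed here, so signal shared between these related genes was not assessed.

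As a group the 11 ER body genes had a median of -2.01, with medians between -2.32 and -1.84 on the 4 arrays (camera adjusted p = 1.11e-20). Camera with an estimated correlation of 0.306 between the genes did not call the list (p = 0.038, adjusted p = 0.304). That version tests on the few residual degrees of freedom left by 4 arrays and the genotype and dye terms. Its missing call therefore cannot tell whether correlation between the genes accounts for the preset result. Fry gave an adjusted p of 0.0199. Adjusted over the list alone, 9 members fell. Some members were found by others in nai1 roots, possibly on these arrays. The group tests and the counts of members that fell are therefore not independent evidence of a change or of its direction.

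**Figure D1:**
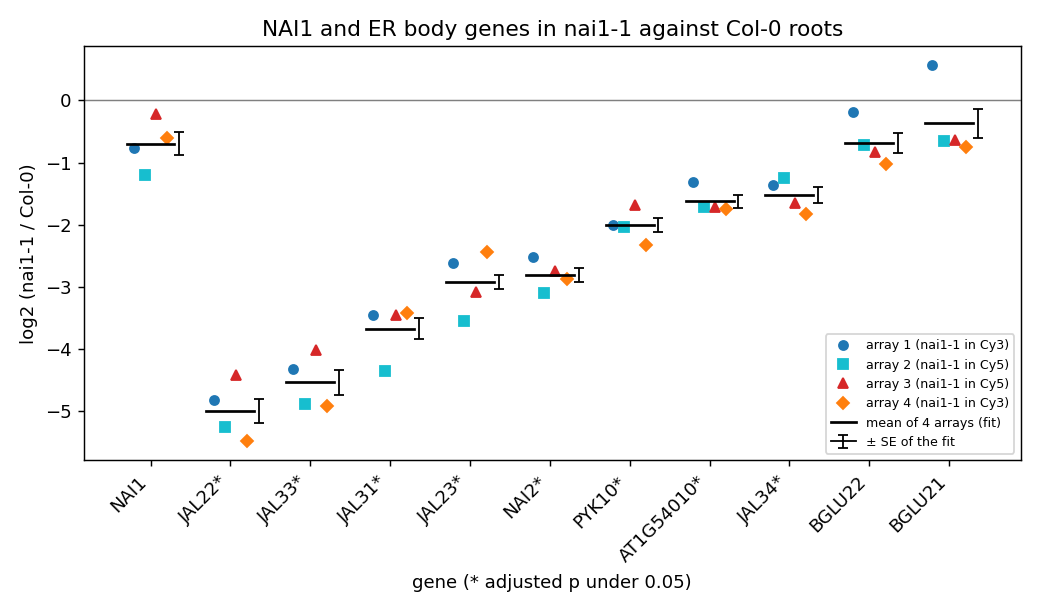
Log2 ratio of nai1-1 over Col-0 (vertical axis) for NAI1 and 10 of the 11 measured ER body genes (horizontal axis; AT1G54020, at 0.06, is not plotted), with 1 symbol per array, a bar at the mean of 4 arrays and an error bar of ± 1 SE from the limma fit. JAL22 is lowest, at -4.99, BGLU21 on array 1 is the only plotted point above 0, and an asterisk marks genes with an adjusted p under 0.05.

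The second question was which other transcripts differed in the mutant. Lower transcripts made up most of the calls: 109 probes were lower and 3 higher in nai1-1, and all 112 had the same sign on 4 arrays (109 higher and 3 lower under the opposite convention). Of the lower probes, 100 fell at least 2-fold, 24 at least 4-fold and 6 at least 8-fold. They included 54 probes with 1 named gene, and 1 named gene was higher. AT1G33760, which encodes an AP2/ERF transcription factor, fell by 3.13 ± 0.22, and BHLH92 (AT5G43650), a basic helix-loop-helix transcription factor, fell 8.57-fold (SE 0.10 on the log2 scale). AT1G66800, a gene of the cinnamyl-alcohol dehydrogenase-like family, fell by 2.66 ± 0.09, and AT1G20310 fell by 2.57 ± 0.10. MSRB6 (AT4G04840), a methionine sulfoxide reductase, fell by 2.29 ± 0.18. The adjusted p-values of these 5 genes lay between 0.0181 and 0.0428. The named gene that rose was AT5G08250, a cytochrome P450 gene, at 1.48 ± 0.09, which is 2.78-fold (adjusted p = 0.0327, higher on 4 of 4 arrays). Among the probes not named here, probe 12950 fell by 4.87 ± 0.14, probe 15258 fell by 2.85 ± 0.20, and probes 19468 and 11294 rose by 1.39 ± 0.11 and 1.16 ± 0.10.

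At an unadjusted p under 0.05, 1651 probes were lower and 1262 higher. The counts depended on the fit: leaving out the 1016 probes with an exact 0 gave 778 probes (645 lower, 133 higher), which included all 112, and leaving out any single array gave 0 in the fit on all probes. Taking arrays 1 and 2 and arrays 3 and 4 as 2 replicates gave 0 on all probes and 121 without exact 0 values, of which 95 were among the 112.

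**Figure D2:**
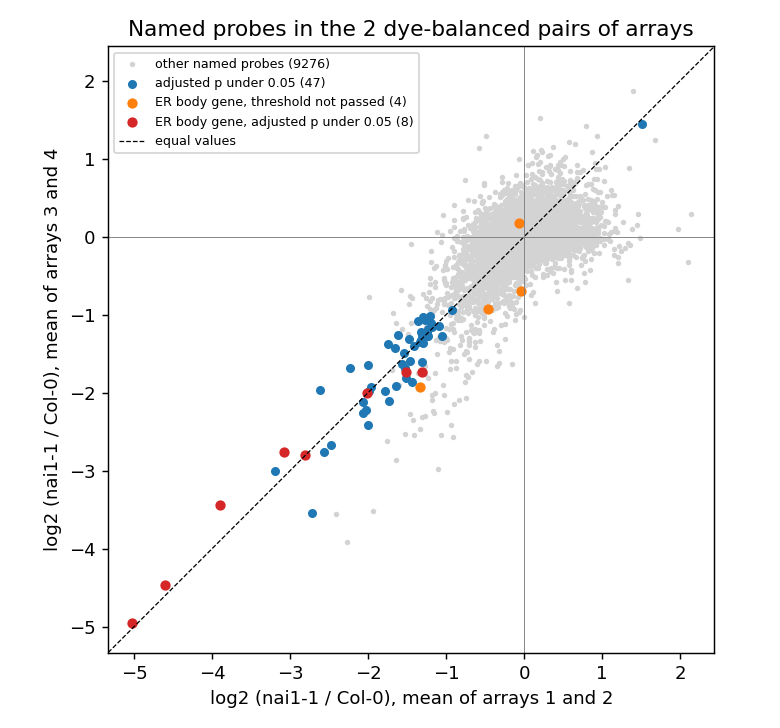
Log2 ratio of nai1-1 over Col-0 for 9335 named probes, as the mean of arrays 1 and 2 (horizontal axis) against the mean of arrays 3 and 4 (vertical axis), each mean holding both dye orientations. The 8 red points are ER body probes with an adjusted p under 0.05, the 4 orange points other ER body probes and the 47 blue points other named probes past the threshold, and the single point called above 0 is AT5G08250.

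The third question was whether other functions or cell types moved with the genotype. In the 7 other lists with at least 3 measured genes, 0 genes passed the threshold over all probes and camera called 0 lists. Each was measured only in part: 15 of 33 beta-glucosidases, 16 of 38 jacalin-related lectins, 6 of 15 heat shock and 8 of 30 ER chaperone genes. For photosynthesis 5 of 31 listed genes were measured, for jasmonate 3 of 27 and for aliphatic glucosinolate synthesis 3 of 18. Fry's adjusted p-values for a change in 1 direction were 0.14 or higher in these lists. Its unadjusted p-values for changes in either direction ran from 0.000759 (other jacalin-related lectins) and 0.000836 (heat shock genes) to 0.527 (photosynthesis genes). Without exact 0 values, 2 of the beta-glucosidases and 2 of the jacalin-related lectins fell and 1 heat shock gene rose, and all 5 of these calls were lost when arrays 1 and 2 and arrays 3 and 4 were also averaged as 2 replicates (adjusted p from 0.0653 to 0.175). Of 15 other beta-glucosidases the median was -0.01 (adjusted p = 0.182). BGLU46 was at -0.83 ± 0.09 and BGLU24 at -0.62 ± 0.12, BGLU15 at -0.39 and BGLU25 at -0.37, and 2 of the 15 fell when adjusted over the list alone. Of 16 other jacalin-related lectins, the family of JAL22, the median was -0.12 (adjusted p = 0.278), and 3 fell and 1 rose when adjusted over the list alone. In that family AT5G35940 was at -1.46 ± 0.35, AT1G52100 at -0.98 ± 0.12, AT3G21380 at -0.50 ± 0.08 and AT1G52070 at 0.39 ± 0.09. AT3G21380 held an exact 0 on array 1.

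Heat shock genes had a median of 0.19 over 6 genes (adjusted p = 0.10), and 1 rose when adjusted over the list alone. Among them AT5G48570, an FKBP-type chaperone gene, was at 0.92 ± 0.08 (adjusted p = 0.0511) and AT1G07400, a small heat shock protein gene, at 0.67 ± 0.23, and AT2G29500 and ATHSP22.0 were at 0.24 and 0.14. Without array 1 the heat shock list was called by camera at the preset correlation (adjusted p = 0.00345, median 0.25). With an estimated correlation its adjusted p was 0.776 there, but that fit called 0 lists and gave the ER body list 0.655. Too few residual degrees of freedom remained for a call, so the 0.776 counts neither for nor against the heat shock list. With 4 arrays the adjusted p was 0.451 with an estimated correlation and 0.181 with fry. The 8 measured genes for ER chaperones and the unfolded protein response had a median of -0.01 and a mean of 0.05, and camera's direction was upward (adjusted p = 0.767). CRT1b, a calreticulin gene, was at 0.34 ± 0.21, and BIP1, an ER chaperone gene, at 0.34 ± 0.17, with 1.18 and 1.05 on array 1. ATERDJ3B was at 0.19 ± 0.08 and BZIP60 at -0.28 ± 0.11.

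Photosynthesis genes, used as markers of shoot tissue, had a median of -0.10 over 5 genes (adjusted p = 0.379), with LHCB4.1 at -0.18, PSAE-1 at -0.12, RCA at -0.10 and SBPASE at -0.09. The 3 measured jasmonate genes had a median of -0.11 (adjusted p = 0.379), with PDF1.2 at -0.11, JMT at -0.11 and THI2.1 at -0.09. The 3 measured genes of aliphatic glucosinolate synthesis had a median of 0.19 (adjusted p = 0.182), with BCAT4 at 0.24, AT2G31790 at 0.19 and AOP3 at 0.16. A list that was not called is not shown to be unchanged.

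Lists with fewer than 3 measured genes were not tested as groups, and 0 of their genes passed the threshold over all probes. The root hair expansins EXPA7 and EXPA18 were at 0.59 ± 0.09 and 0.38 ± 0.14, and 1 of these 2 rose when adjusted over the list alone. WRKY53, a transcription factor of the salicylate and defence list and its single measured gene, was at -1.31 ± 0.28 (adjusted p = 0.18). Its means were -0.75 on arrays 1 and 2 and -1.86 on arrays 3 and 4. With 1 measured gene, adjusting over the list alone adjusts nothing, and the unadjusted limma p was 0.00795. Without exact 0 values WRKY53 fell (adjusted p = 0.0334) and EXPA7 rose (adjusted p = 0.0357), and 0 other genes of these lists passed. With pairs of arrays also averaged neither passed (adjusted p = 0.175 and 0.147). For indole glucosinolate and tryptophan synthesis, AT2G04400 was at -0.30 ± 0.08 and UGT74B1 at -0.23 ± 0.09, and 1 of the 2 fell when adjusted over the list alone. In the iron deficiency list BHLH101 was at 0.33 ± 0.15 and AT3G13610 at 0.18 ± 0.12. In the sulfur deficiency list AT1G04770 was at 0.22 ± 0.18, with means of -0.11 on arrays 1 and 2 and 0.55 on arrays 3 and 4. In the endodermis list GSO1 was at 0.20 ± 0.14, with means of 0.44 on arrays 1 and 2 and -0.04 on arrays 3 and 4. The basic helix-loop-helix genes most related to NAI1, AT4G37850 and AT2G22750, were at -0.06 ± 0.09 and -0.02 ± 0.09. No member of the lists for leaf and wound-induced ER body genes, phosphate starvation, nitrate assimilation, vascular tissue, or cell division and root tip had a named probe, so these 5 lists were not analysed here.

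The dye term was tested as a control quantity with no genotype in it. It passed the threshold for 0 probes with limma, with 1217 probes at an unadjusted p under 0.05. That fit held the probes with an exact 0, without which the genotype count rose from 112 to 778. The dye term was not tested without them, so the 0 does not show that gene-specific dye bias is absent. The named genes with the largest dye effects in Cy5 over Cy3 were AT1G74140 at -0.98, AT1G48700 at -0.91 and XIJ, a myosin gene, at -0.82. A dye effect below -1 occurred in 469 probes, all without a name here, and in 0 named probes.

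Agreement between arrays was described by Pearson correlation across probes after turning. Across named probes r was 0.39 for arrays 1 and 2, 0.33 for arrays 1 and 3, 0.50 for arrays 1 and 4, 0.51 for arrays 2 and 3, 0.54 for arrays 2 and 4 and 0.75 for arrays 3 and 4. Across all 22575 probes, which include the 469 with the large dye effect, r ranged from -0.13 to 0.66, with a median over the 6 pairs of 0.138. Of the named probes, 25% had the same sign on 4 arrays. Chance gives 12.5% for 4 independent arrays and a larger share if arrays share RNA.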

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

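The outlier test on single arrays was fixed in advance, and the tests of paired arrays and of sign patterns were chosen after the results had been seen. Among 70 values tested (named genes, probes and list medians), 7 had 1 array apart from the other 3 by Dixon's test, where chance gives about 3.5. Array 1 stood apart in 4 of them, array 2 in 2, array 3 in 1 and array 4 in 0.

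Array 1 gave 0.56 for BGLU21 against -0.76 to -0.64 on the other arrays, 1.18 for CRT1b against 0.02 to 0.09, 0.35 for ATERDJ3B against 0.13 to 0.16, and -1.32 for AT1G54010 against -1.75 to -1.71. Array 2 gave -4.35 for JAL31 against -3.46 to -3.42, and 0.48 for AT2G31790, a glucosinolate synthesis gene, against 0.07 to 0.12. Array 3 gave -0.17 for BGLU24 against -0.80 to -0.70. Over all 9247 named probes without an exact 0, 530 (5.73%) had 1 array apart, where chance gives about 1 in 20. That array was array 1 for 257 probes, array 2 for 138, array 3 for 90 and array 4 for 45. The order of these counts follows the spread of the arrays (median absolute deviations of 0.388, 0.325, 0.218 and 0.185). A wider array can stand apart more often, which was not tested. A check of whether abundant transcripts were shifted on array 1 could not be made, since 1 ribosomal protein gene had a named probe.

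Arrays 1 and 2, and arrays 3 and 4, deviated together: the difference between arrays 1 and 4, which share a dye orientation, correlated across named probes with the difference between arrays 2 and 3, which share the other (Pearson r = 0.224, Spearman rho = 0.158), and r was 0.199 over the 8865 named probes not called without exact 0 values. These differences share no array, so artefacts that add to the ratios of single arrays would give values near 0. A constant dye bias cancels in each, and one that differs between the pairs would make the correlation negative. These 3 causes alone would therefore not give the positive values, but the values do not show them absent. AT1G74140, picked for its large dye effect, had 1.51 and -1.33 on arrays 1 and 2 against -0.23 and 0.85 on arrays 3 and 4. AT1G48700 and XIJ, picked in the same way, also had the larger opposite values on arrays 1 and 2. Dye-swapped pairs of shared RNA remain open as a candidate explanation, under which the 4 arrays may hold 2 independent replicates. A dye bias that differs between arrays 1 and 3 and arrays 2 and 4, or a shared slide or day for each pair, would also give a positive correlation, and these were not tested. Arrays 1 and 2 were also wider (median absolute deviations of 0.388 and 0.325) than arrays 3 and 4 (0.218 and 0.185). A difference in scale between arrays would multiply any shared genotype signal and could give a positive correlation too, which was not tested.

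The 8 sign patterns of the 4 arrays were each fitted without a dye term. The real one gave 394 probes and the highest of the others 0, so 1 of 8 patterns gave as many. With 8 patterns no share can be under 0.05. With the dye term, the other 2 patterns with balanced dyes gave 0 probes, against 112 for the real one.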

How the results depend on the processing

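Alternatives that average arrays as 2 replicates or combine leaving out exact 0 values with another choice were chosen after seeing the data, as were the list test without array 1 at an estimated correlation and the correlation between arrays over named probes; the others were planned. The main count was 112 probes (109 lower, 3 higher), and the cause of each change below was not tested unless stated. Median centring and array weights gave the same 112, and a 2-fold minimum on the estimate gave 103. Larger counts came without the dye term (394: 333 lower, 61 higher), with quantile normalization (369: 328, 41), robust eBayes (531: 456, 75), named probes alone (570: 421, 149), gene-level values (581: 426, 155) and the other pairing of opposite dyes, arrays 1 with 3 and 2 with 4 (391: 362, 29). Leaving out probes with an exact 0 gave 778 (645, 133), and doing so without the dye term 664 (548, 116). With the 1016 probes that held an exact 0 the fit's prior degrees of freedom were 2.27, and without them 4.86. All 112 probes were among the 394, 369, 531, 391, 778 and 664.

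The count was 0 (0 lower, 0 higher) with limma after scaling to 1 median absolute deviation (3212 at an unadjusted p under 0.05), with a tested 2-fold minimum (158), at a threshold of 0.01 (2913), with unturned values (1158), and with arrays 1 and 2 and arrays 3 and 4 averaged as 2 replicates (2261). The last gave 121 (117, 4) without exact 0 values, 95 of them among the 112. Leaving out each array in turn gave 0 in every case (1754 to 3311 unadjusted), and without exact 0 values 698, 205, 222 and 939 for arrays 1 to 4 (630, 192, 209 and 632 lower; 68, 13, 13 and 307 higher). Of the 112, 112, 105, 103 and 112 were called in these 4 fits.

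The 62 named genes and probes had 1415 tested values under the alternatives: 1196 kept direction and side of the threshold, 144 were no longer past it, 58 were newly past it and 17 changed sign without passing it. Of 248 means of array pairs with no test, 12 changed sign. The 18 called genes and probes had 0 sign changes. The 17 were in 6 genes that did not pass in any of these fits. When an array was left out, JMT ranged from -0.215 to 0.0034, SBPASE from -0.23 to 0.0487, XIJ from -0.37 to 0.30 (0.0413 with quantile normalization), AT2G22750 from -0.0924 to 0.0448, AT1G48700 from -0.16 to 0.44 and AT1G74140 from -0.0731 to 0.48. Camera's direction turned, with no call, for ER chaperones without array 1 or 3 (medians from -0.0662 to 0.0904 when an array was left out) and for photosynthesis genes without array 2 (medians from -0.16 to -0.0705). The 144 were the 18 called genes and probes under the 8 settings with 0 calls. All 18 remained called without exact 0 values, also after leaving out any array or averaging pairs. NAI1 had adjusted p-values from 0.0428 to 1 and PYK10 from 6.5e-05 to 0.411. The number of lists called was 1, but 0 with an estimated correlation, where the ER body list (median -2.01) had an adjusted p of 0.304, and 1 to 2 when an array was left out. The second was heat shock without array 1 (adjusted p = 0.00345), whose median was 0.19 with 4 arrays and ranged from 0.15 to 0.25 when an array was left out. With an estimated correlation, added later, heat shock without array 1 had an adjusted p of 0.776. In that fit 0 lists were called and the ER body median was -2.09. Camera with an estimated correlation had few residual degrees of freedom, so its missing calls decide nothing about these lists. The median correlation between arrays was 0.138 over all probes and 0.504 over named probes. The dye term passed for 0 probes in both settings (1217 unadjusted). With 0 missing values, keeping probes with missing values could not be tried. Values of single genes at gene level and with unturned arrays were not computed. The main fit was already paired within arrays, since each ratio compares both genotypes on 1 array. Beyond the fits that averaged pairs of arrays, a fit with a term for these pairs was not run. Signal over background was not analysed here, so its limits are unknown.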

Other observations

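The tests of neighbouring genes below were chosen after the results had been seen, and the list of rapid response genes was written after its theme had been noticed among the largest changes. Genes in the next paragraph were picked after their values were seen.

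Beyond the genes named by rule, genes of several other kinds fell in nai1-1 (n = 4 arrays, lower on 4 of 4). GTR1 (AT3G47960), a glucosinolate transporter, fell by 1.78 ± 0.10 (limma adjusted p = 0.032). MSRB8, a second methionine sulfoxide reductase beside MSRB6, fell by 1.53 ± 0.13 (adjusted p = 0.0464). SWEET16, a vacuolar sugar transporter, fell by 1.33 ± 0.10 and PUP18, a purine permease, by 1.66 ± 0.14. FAMT (AT3G44860), a farnesoic acid methyltransferase, fell by 1.39 ± 0.12 and its neighbour AT3G44870, of the same methyltransferase family, fell 4.60-fold (SE 0.13 on the log2 scale). AT1G30720 and AT1G30730, neighbouring genes for berberine bridge enzyme-like proteins, fell 2.91-fold and 3.02-fold.

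Of the 54 called lower genes, 11 had another called gene within 5 annotated protein-coding genes (order from TAIR10.1), against a median of 0 and a 95% range reaching 4 in 10000 random draws from 9242 measured genes. The highest draw gave 12, and 1 draw gave 11 or more. They were JAL22 with JAL23, JAL31 with JAL33 and JAL34, FAMT with AT3G44870, AT1G30720 with AT1G30730, and AT5G14700 with AT5G14730. Several are related copies, and signal shared between related probes may contribute, which was not tested because probe sequences were not analysed here.

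Several of the largest falls outside the ER body list brought to mind rapid touch and wound responses. A list of 61 such genes was written, from which the genes already noticed were left out. Its 10 measured members had a median of -1.48 (camera p = 3.63e-14, and p = 0.0943 with an estimated correlation of 0.653). The second p-value rests on few residual degrees of freedom and cannot decide whether co-variation accounts for the first. CML38 and CML37, calmodulin-like genes, were at -2.19 ± 0.23 and -1.79 ± 0.27, PUB23 and PUB22, U-box ubiquitin ligase genes, at -1.89 ± 0.25 and -1.65 ± 0.21, and the zinc finger gene STZ (ZAT10) at -1.32 ± 0.20. The other 5 were AR781 at -1.64 ± 0.24, ZAT7 at -0.98 ± 0.13, WRKY22 at -0.72 ± 0.08, PUB24 at -0.50 ± 0.09 and WRKY6 at 0.02 ± 0.16, the last with 0.62 on array 1 and between -0.23 and -0.12 on the others. With limma, 0 of the 10 passed in the fit on all probes, 8 fell without exact 0 values, and 0 passed there when arrays were averaged as 2 pairs.

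The list median was -1.06 on arrays 1 and 2 and -1.82 on arrays 3 and 4, each below all 10000 random lists, and the median difference between the pairs was -0.66, against a random range of -0.21 to 0.18. Random lists hold mostly unrelated genes, while the listed genes co-vary, so these ranges are too narrow to serve as a test. Genotype and a difference between the pairs of arrays therefore cannot be told apart from shared variation of these genes by this comparison. Handling at harvest, to which such genes can respond, was not recorded in the labels and was not tested. Each reading is a hypothesis, since the theme was found in the same data.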
